A study of Mus musculus with 2 samples.

How the data were processed

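MicroRNA sequencing libraries were made from cerebral cortex tissue of female 5xFAD mice with a multiplexed small RNA protocol and a fragment size range under 30, per the labels. The sex is taken from the sample descriptions, because the sex field of the labels reads not collected. Each of the 2 libraries had its own table. The deposited tables hold raw read counts, not normalized, for 2202 microRNA genes of GENCODE M21 on the mouse genome build mm10, per the files that describe each library. Per the file layout, each gene has 3 counts (both strands together, the strand of the gene, the opposite strand), and 4 further rows hold unmapped, multimapping, unassigned and ambiguous reads. This layout is that of gene counts from STAR; the aligner and its settings are not given in the sources used here. The labels cite an adapter-trimming document that differs between the libraries, so trimming may not have been identical. All 2202 gene identifiers matched the GENCODE M21 annotation used here, which gave symbols, positions and host genes.

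The count on the strand of the gene was used, because it held nearly all gene reads of genes that have no other microRNA gene opposite. A count joins both arms of a hairpin, so mature arms were not told apart. Rows that name no gene were left out of library sizes and tests. Multimapping reads made up 50.0% and 48.4% of all reads and unmapped reads 14.8% and 13.6%. Mapped reads outside microRNA genes made up 2.74% and 3.51%, with multimapping reads not included. Where the multimapping reads lay is not given, so they need not come from microRNA genes. Reads with several positions were not assigned to a gene. Genes with a copy number in their symbol (46 detected and 96 not detected, 3.42% and 3.60% of gene reads) are uncertain for this reason. Counts differed between the libraries far beyond sampling noise (chi-square per degree of freedom 1815, 555 degrees of freedom), so the libraries were counted as 2.

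The libraries form 1 group, and no contrast between groups exists, so no group test was made. CPM was computed over the reads assigned to microRNA genes. A gene was called detected with at least 10 reads in each library. Ratios of replicate 2 to replicate 1 are log2 of CPM plus a pseudocount of 1, with TMM effective library sizes from edgeR, and understate the difference of scarce genes. Their 95% intervals come from the exact Clopper-Pearson interval of the read split, without a pseudocount. Genes with at least 10 reads in total were compared between the libraries with an exact two-sided binomial test given the TMM sizes, with Benjamini-Hochberg adjustment at 0.05. That test compares libraries, and it treats reads as independent, so it calls small differences of abundant genes. The spread beyond counting error was estimated as edgeR's common dispersion with an intercept only and given as its square root.

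A total of 15 gene lists (cell types, tissues, clusters and families, and microRNAs linked to Alzheimer's disease) were fixed before the data were examined. For each, the share of gene-assigned reads per library and the median log2 ratio of detected members were computed, the latter with its percentile among 10000 random lists of the same size drawn within 10 bins of mean expression. A list was matched by symbol, so miR-146a and miR-92a, which carry other symbols in this annotation (Mir146, Mir92-1 and Mir92-2), were not counted; an alternative with them was added after seeing the data. Some genes stand in more than 1 list. The genes named are the 15 with the highest mean CPM, up to 4 members of each list with the highest mean CPM and list members without reads, and the 5 genes on each side with the largest log2 ratio among those past the binomial test with a mean of at least 10 CPM. Other genes named were chosen after their values were seen: the remaining members of the epithelium list, Mir146, Mir92-1, Mir92-2, Mir341, Mirlet7f-1, and Mir124a, Mir9, Mir128, Mir138 and miR-7 family members, Mir203, and genes named for reads on the opposite strand.

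Alternatives fixed beforehand were reads of both strands, omission of multi-copy genes or of the most abundant gene, each library alone, other detection minimums and pseudocounts, all reads as the denominator, DESeq2 size factors or library totals in place of TMM, and DESeq2's fitted dispersion. Added after seeing the data were ratios corrected for a lowess trend (span 0.667) on hairpin GC content, a 2-fold criterion, omission of the epithelium list, and the list members under other symbols. Which lists are treated as main results in the account of these alternatives was also chosen after seeing the data. Permutation tests used 100000 permutations, with Benjamini-Hochberg adjustment over a family of 7 tests; they were two-sided for correlations and one-sided for the difference between neighbouring genes. Hairpin sequences came from the annotation's transcripts.

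The procedure was tested on simulated data for the comparison of replicate 2 with replicate 1, with 425 genes of which 200 were changed 2-fold. It recovered 93% of the genes raised and 83% of those lowered, and called 4% of unchanged genes. These counts were drawn with counting error only and compared by library totals without TMM. The rates therefore do not hold for the wider spread between the real libraries. A simulated coefficient of variation of 60% was estimated as 58.6%, and 20% as 20.6%. Tools were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.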

Results

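Small RNA from the cerebral cortex of female 5xFAD mice was profiled by microRNA sequencing in 2 libraries. 5xFAD is a mouse line that carries human APP and PSEN1 transgenes with mutations that cause familial Alzheimer's disease, and the labels call these mice heterozygous. The labels give the libraries as biological replicates 1 and 2 of 1 group. They come from separate biosamples that carry the same donor identifier, so it is not established that they come from separate animals, and every test between them measures only the spread between these 2 libraries. Age is not given in the labels, and the sex comes from the descriptions, since the sex field reads not collected. No wild-type library was analysed here, so the values describe the microRNA content of this cortex and how far the replicates differed, not an effect of the transgenes.

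Replicate 1 held 15313784 reads and replicate 2 held 17535610 reads. Of these, 4974384 reads (32.5%) and 6049309 reads (34.5%) were assigned to the strand of a microRNA gene. Reads that mapped to several places made up 50.0% and 48.4% and were assigned to no gene, so the counts of genes whose mature sequence occurs in several copies are uncertain. Values are reads per gene, which join both arms of a hairpin, scaled to the total of reads assigned to microRNA genes (CPM). At least 1 read was found for 739 and 759 of 2202 annotated microRNA genes, and 425 genes had at least 10 reads in each library. With this depth, counting error is small for abundant genes; 95% intervals are exact Clopper-Pearson intervals and cover counting error only, since PCR copies of reads are not independent molecules.

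By gene-assigned reads, which leave out reads with several positions, the most abundant microRNA gene in this cortex was Mir139. Multi-copy families such as Mir124a and Mir9 cannot be ranked against it. Mir139 lies in an intron of the phosphodiesterase gene Pde2a on chromosome 7 (mm10, positions 101475376 to 101475443). It took 11.8% of gene-assigned reads in replicate 1 (interval 11.79 to 11.84) and 15.01% in replicate 2 (14.98 to 15.04), or 134107 ± 22584 CPM (SD, n = 2). Next came Mir127, a maternally expressed gene of the imprinted Dlk1-Dio3 cluster (chromosome 12, 109592846 to 109592915, outside annotated host genes), at 48793 ± 1418 CPM. Mir132, which is induced by neuronal activity, stood at 43239 ± 4792 CPM and lies in an intron of the non-coding gene 1700016P03Rik on chromosome 11 (75173682 to 75173747). Mir29a, a published regulator of the beta-secretase gene Bace1, lay at 28489.6 ± 9262 CPM (chromosome 6, 31062660 to 31062747).

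Of the 15 most abundant genes, 5 belonged to the let-7 family, a group of hairpins with closely related mature sequences that is high in differentiated cells. Mirlet7b had 46104 ± 1245 CPM, Mirlet7g 45109 ± 33095 CPM, Mirlet7i 42125 ± 20849.8 CPM, Mirlet7d 26888 ± 13849 CPM and Mirlet7e 18874 ± 3261 CPM. The other genes among the 15 were Mir744 at 36459 ± 14184 CPM, Mir30d at 26857 ± 11872 CPM, Mir770 at 19112 ± 1819 CPM, Mir23b at 17771 ± 5869 CPM, Mir652 at 16457 ± 5269 CPM and Mir99a at 16430.1 ± 8917 CPM. The 10 most abundant genes together took 49.5% of gene-assigned reads in replicate 1 and 46.1% in replicate 2 (47.8% ± 2.38, SD, n = 2). Ranks among neighbouring genes of this group are not resolved where SDs are this wide, as for Mirlet7g.

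**Figure D1:**
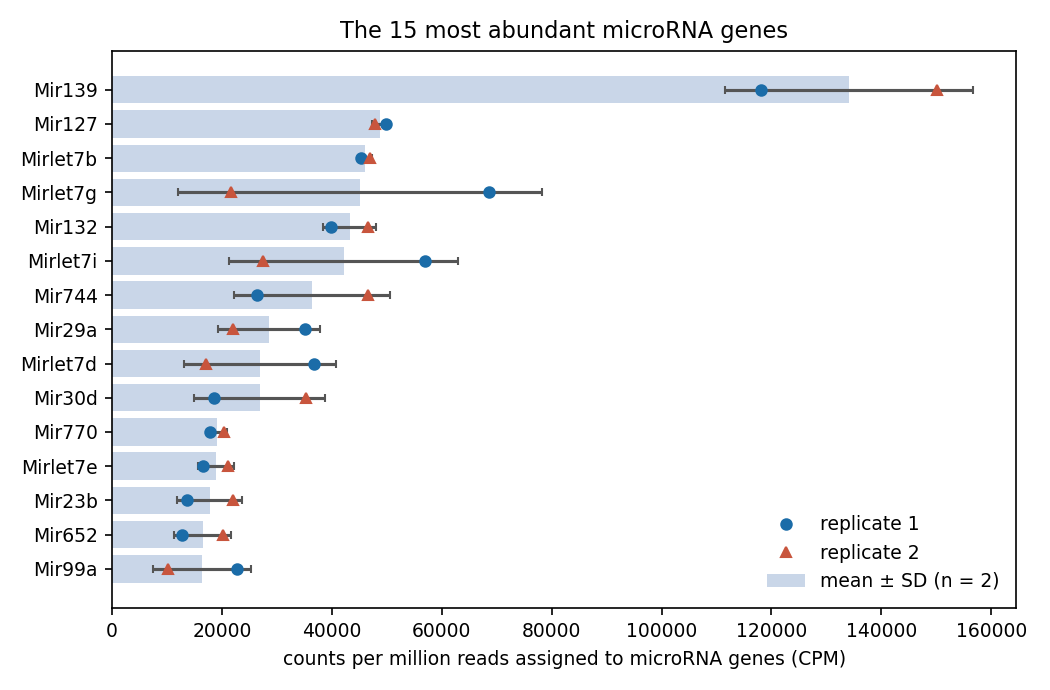
Levels of the 15 most abundant microRNA genes in CPM. Bars give the mean of the 2 libraries, error bars the SD (n = 2), and points the values of replicate 1 (circles) and replicate 2 (triangles). Mir139 stands above all others at a mean of 134107 CPM, and Mirlet7g has the widest error bar, with an SD of 33095 CPM.

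Marker microRNAs of cell types in the cortical pool were examined with lists fixed before the data were examined. The lists differ in size, and single genes can dominate them. Their shares therefore do not measure or rank what each cell type contributes. Genes of the neuron list took 6.05% of gene-assigned reads in replicate 1 and 6.99% in replicate 2 (6.52% ± 0.659, SD, n = 2), and 10 of its 13 members were detected, that is, had at least 10 reads in each library. Mir132 led the list, followed by Mir128-1, in an intron of R3hdm1, at 7129 ± 281 CPM, Mir129-2 at 3746 ± 817 CPM and Mir138-1 at 3229 ± 882 CPM. The 3 copies of Mir124a, the best-known neuronal microRNA, had only 15 reads in replicate 1 and 32 reads in replicate 2; this family was singled out after its values were seen, and its hairpins share 32 identical nucleotides, so its reads can fall among the reads with several positions. The neuron list's median log2 ratio of replicate 2 to replicate 1 was -0.12 although its share was higher in replicate 2; it was -0.74 without multi-copy genes and 0.02 with scaling by library totals. In the binomial comparison of the libraries, 5 members were higher in replicate 1, 4 were higher in replicate 2 and 4 did not pass; 10 passed when adjusted over the list alone.

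Oligodendrocyte microRNAs took 0.808% and 0.868% of gene-assigned reads (0.838% ± 0.0423, SD, n = 2). Mir219a-2 and Mir338, both needed for oligodendrocyte maturation, stood at 5713 ± 894 CPM and 2352 ± 521 CPM, and Mir3099 at 301 ± 48.1 CPM. This share fell to 0.0319% when reads of both strands were counted together, because Mir219a-2 and Mir338 have another annotated microRNA gene opposite, and to 0.275% without multi-copy genes. The median log2 ratio of the list was 0.19, and turned to -0.19 with the trend on hairpin GC content removed and to -0.20 without multi-copy genes; 1 member was higher in replicate 1, 2 were higher in replicate 2 and 1 did not pass (3 passed when adjusted over the list alone).

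Vascular microRNAs took 1.78% and 1.96% (1.87% ± 0.13, SD, n = 2). Mir23a had 10015 ± 4363 CPM, Mir126a, which lies within the endothelial gene Egfl7, had 4369 ± 1628 CPM, and the smooth-muscle microRNAs Mir143 and Mir145a had 3532 ± 1489 CPM and 448 ± 5.26 CPM. The vascular median log2 ratio was -0.16 (0.06 with both strands counted together), against a higher share in replicate 2; 3 members were higher in replicate 1 and 2 in replicate 2, with 5 past the threshold also when adjusted over the list alone. The higher share rested on Mir23a, with a log2 ratio of 0.78, whereas Mir126a, Mir143 and Mir145a had -0.92, -1.03 and -0.16. Leukocyte and microglial microRNAs took 0.0862% and 0.127% (0.106% ± 0.0286, SD, n = 2), led by the lymphocyte microRNA Mir150 at 781 ± 370 CPM, Mir155 at 230.3 ± 45.1 CPM, Mir142 at 28.4 ± 20.5 CPM and the myeloid Mir223 at 17.1 ± 15.95 CPM. Mir150 had a log2 ratio of 0.87, whereas the other 4 tested members were higher in replicate 1 and the list median was -0.75, or 0.16 over members with at least 100 reads in each library (5 past the threshold when adjusted over the list alone). The list as matched leaves out the inflammatory miR-146a, which carries the symbol Mir146 and had 10374 reads in replicate 1 and 7160 in replicate 2 (log2 ratio -0.95), beside 4286 and 7659 reads for the whole list. With Mir146 added after seeing the data, the share was higher in replicate 1, at 0.295% against 0.245%, and the median was -0.85. The weakly established astrocyte list took 0.0265% and 0.0462% (0.0363% ± 0.0139, SD, n = 2), with Mir193b at 333 ± 125.6 CPM and a median log2 ratio of 0.71; 2 members were higher in replicate 2 and 1 did not pass (2 passed when adjusted over the list alone).

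MicroRNAs of tissues that a cortex dissection should lack were mostly scarce. The 14 embryonic stem cell genes had 10 and 7 reads in all, 8 of them had none in either library, and none was detected. For a gene with no reads in a library, a count of 0 allows up to 3 reads. The cardiac and skeletal muscle list took 0.00312% and 0.0015%, and Mir1a-1, Mir1a-2, Mir133a-1, Mir133a-2 and Mir208a had no reads; the first 4 are multi-copy genes. Mir206 had 72 and 76 reads and Mir499 had 80 and 12, so Mir499 was higher in replicate 1 and Mir206 did not pass; the list's median log2 ratio was -1.47 over these 2 genes (1 passed when adjusted over the list alone), at percentile 0.22 of matched random lists and 0.84 with the trend on hairpin GC content removed. The liver and gut list took 0.00722% and 0.00595%, with Mir122 at 24.0 ± 10.03 CPM, a median log2 ratio of 0.02 that turned to -0.74 without multi-copy genes, -0.41 with the GC trend removed and -0.06 with DESeq2 size factors, and 1 member higher in each library and 1 not past the threshold (2 passed when adjusted over the list alone). The erythroid list took 0.00193% and 0.00165%, with 46 and 30 reads for the red-cell microRNA Mir451a and 49 and 69 for Mir486; its median log2 ratio was -0.42, 1 member was higher in replicate 1, and 1 did not pass (1 passed when adjusted over the list alone). Choroid plexus and ependymal genes took 0.418% and 0.236% (0.327% ± 0.129, SD, n = 2). Their leading member, Mir204 in an intron of Trpm3, had 2122 ± 545 CPM and the multiciliated-cell microRNA Mir34c had 838 ± 672 CPM. The choroid plexus median log2 ratio was -1.02, with 5 members higher in replicate 1 and 1 not past the threshold (5 when adjusted over the list alone).

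The list of epithelial and sensory-organ microRNAs differed most between the libraries: it took 1.504% of gene-assigned reads in replicate 1 and 0.112% in replicate 2, a 13.4-fold difference in share. Mir183, Mir182 and Mir96, a cluster on chromosome 6 that is high in sensory organs, had log2 ratios of replicate 2 to replicate 1 of -4.48 (38688 and 2312 reads), -4.66 and -6.12. The miR-200 family, which maintains epithelial identity, followed, with Mir429 at -4.32, Mir200a at -5.41, Mir200b at -2.70, Mir200c at -3.65 and Mir141 at -4.98. Mir375, a microRNA of endocrine cells, had a ratio of -0.94 (interval -1.04 to -0.84), and Mir205, a microRNA of squamous epithelium, had 34 and 69 reads and did not pass the test. In all, 9 of the 10 members were higher in replicate 1 and 1 did not pass, while 10 passed when adjusted over the list alone. The list's median log2 ratio over 9 detected members was -4.32, lower than in each of 10000 random lists of the same size and expression. Random lists drew genes singly, whereas the miR-183 and miR-200 genes lie in genomic clusters. The members therefore need not be independent, and the comparison may overstate how unusual the list is. Across the detected genes, the log2 ratio also rose with hairpin GC content (Spearman rho 0.488), and with that trend removed the list's median was -4.09.

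**Figure D2:**
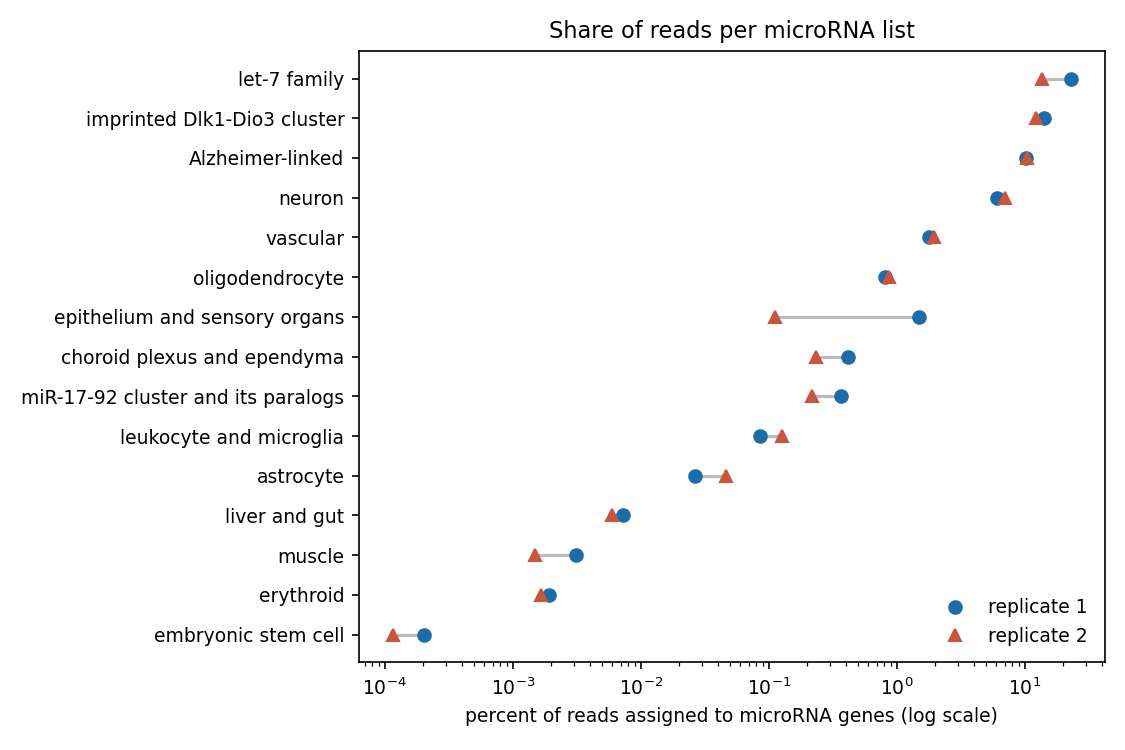
Share of reads assigned to microRNA genes, in percent on a log axis, taken by each of 15 lists in replicate 1 (circles) and replicate 2 (triangles), each a single library without an error bar. The epithelium and sensory organs list lies at 1.504% and 0.112%, the widest gap of the 15 lists, while the embryonic stem cell list lies lowest.

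The listed microRNAs of the imprinted Dlk1-Dio3 cluster on chromosome 12, a large brain-expressed array transcribed from the maternal allele, took 14.3% and 12.2% of gene-assigned reads (13.2% ± 1.49, SD, n = 2). Of 46 listed genes 42 were detected. Among the listed genes Mir127 led, with Mir487b at 14584 ± 8490.2 CPM, Mir434 at 12298 ± 8175 CPM and Mir541 at 10182 ± 156 CPM next. The list leaves out Mir770, which lies in the imprinted transcript Meg3 of the same cluster. At 19112 ± 1819 CPM (88675 and 123396 reads), Mir770 was more abundant than Mir487b, so the shares given here are too low for the whole cluster. The members went both ways between the libraries: 18 were higher in replicate 1, 18 were higher in replicate 2 and 8 did not pass (36 passed when adjusted over the list alone), with a median log2 ratio of -0.02, which was 0.12 with library totals and 0.07 with the GC trend removed. Mir434 had a ratio of -1.61 (interval -1.63 to -1.59), and Mir341, another member, had 0.82 (0.79 to 0.85).

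The let-7 family took the largest share of any list, 22.99% of gene-assigned reads in replicate 1 and 13.66% in replicate 2 (18.3% ± 6.60, SD, n = 2). All 12 genes were detected, and 11 were higher in replicate 1 while Mirlet7e was higher in replicate 2; these counts were 8 and 4 when the libraries were scaled by their totals, and 11 and 1 with DESeq2 size factors. All 12 passed also when adjusted over the list alone. Mirlet7f-1 had the lowest log2 ratio, -3.16, Mirlet7g had -1.80 and Mirlet7b had -0.08. Mirlet7f-1 is a multi-copy gene that shares 22 identical nucleotides with another hairpin, so its count is uncertain. The median, -0.90, lay at percentile 1.14 of random lists matched on expression. Without multi-copy genes the median was -1.21, at percentile 0.58. With the trend on hairpin GC content removed over all 12 genes, the median was -0.52, at percentile 2.68, which no longer passed the lower limit of 2.5. Random lists drew genes singly, whereas some let-7 genes lie close together, such as Mirlet7d and Mirlet7f-1. These percentiles may therefore be too extreme.

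The miR-17-92 cluster and its paralogs, which are linked to proliferation, took 0.371% and 0.217% (0.294% ± 0.109, SD, n = 2). Mir93, within the replication gene Mcm7, led at 1878 ± 946 CPM, followed by Mir17 at 432.8 ± 110.1 CPM. Of 9 tested members 4 were higher in replicate 1 and 5 did not pass (4 passed when adjusted over the list alone), and the median log2 ratio was -0.66, with 8 of 9 ratios below 0 and 6 of 9 with scaling by library totals. The matched list leaves out miR-92a, a core member of the cluster, whose genes Mir92-1 and Mir92-2 went the other way, with log2 ratios of 1.29 and 1.14; with both added after seeing the data, 4 members were higher in replicate 1, 2 were higher in replicate 2 and 5 did not pass (6 passed when adjusted over the list alone), and the median was -0.38.

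MicroRNAs linked in published work to App, Bace1, tau or inflammation took nearly the same share in both libraries, 10.27% and 10.37% (10.3% ± 0.0707, SD, n = 2). After Mir132 and Mir29a, the list was led by Mir328 at 9533 ± 5816 CPM and by the p53-regulated Mir34a at 4718 ± 722 CPM. Log2 ratios were 0.09 for Mir132, -0.81 for Mir29a, 1.19 for Mir328 and -0.45 for Mir34a. The near-equal share thus hides opposite shifts of single members. Mir155, an inflammatory microRNA that also stands in the leukocyte list, had 1304 and 1200 reads. Of 30 members, 13 were higher in replicate 1, 9 were higher in replicate 2 and 8 did not pass (23 passed when adjusted over the list alone). The median log2 ratio was -0.33, at percentile 6.29, and 0.02, at percentile 50.7, with the GC trend removed; over members with at least 100 reads in each library it was -0.06, at percentile 42.5. This list also leaves out Mir146; with it added, the shares were 10.47% and 10.48% and the median was -0.36.

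Over the 425 detected genes, levels in the replicates were closely related (Pearson r 0.952 and Spearman rho 0.945 of log2 of CPM plus 1, across genes, which are not independent replicates). The spread beyond counting error was nevertheless wide, with a biological coefficient of variation of 53.1% by edgeR's common dispersion and 34.8% by DESeq2's fitted dispersion. Of the detected genes, 185 lay within 1.5-fold of equal levels and 130 differed at least 2-fold, 83 of them higher in replicate 1 and 47 in replicate 2. An exact two-sided binomial test per gene with Benjamini-Hochberg adjustment found 60.6% of 556 tested genes apart beyond counting error, 161 higher in replicate 1 and 176 in replicate 2; the rest did not pass. The balance depended on scaling: genes higher in replicate 1 made up 47.8% of those apart with TMM, 53.2% with DESeq2 size factors and 40.5% with library totals. With a 2-fold difference required as well, a criterion added after seeing the data, the share was 27.9%, with 88 genes higher in replicate 1 and 67 in replicate 2. The median log2 ratio of detected genes was 0.08, and scaling by library totals shifted it to 0.20.

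The genes with the largest ratios toward replicate 1 were Mir96, Mir200a, Mir141 and Mir182 of the epithelial list and Mir26a-1, in an intron of Ctdspl, with 628 and 26 reads and a log2 ratio of -4.71 (interval -5.64 to -4.45); Mir26a-1 shares 25 identical nucleotides with its second copy and its count is therefore uncertain. Toward replicate 2 the largest ratio was that of Mir301, in an intron of Ska2, with 6 and 114 reads and a log2 ratio of 3.07 (adjusted p = 2.19e-20, exact binomial test). Mir99b, in an intron of Spaca6 beside Mirlet7e, had a ratio of 2.18 (interval 2.16 to 2.20) at 13756 ± 12959 CPM. The ratios of Mir1930, Mir3072 and Mir346 were 1.87, 1.81 and 1.56. Over all detected genes, ratios were related to hairpin GC content: when these genes were divided into 3 groups by GC content, the lowest group had a median log2 ratio of -0.70 and the highest had 0.52.

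**Figure D3:**
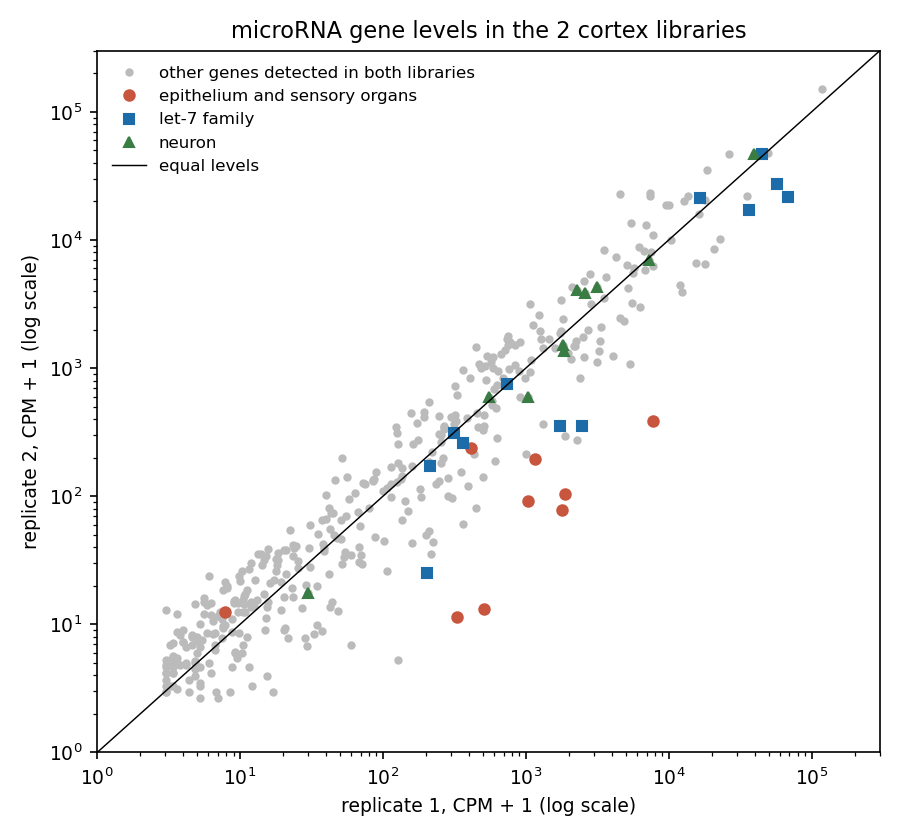
Level of each of the detected microRNA genes in replicate 1 (horizontal axis) and replicate 2 (vertical axis), as CPM plus 1 on log axes (scaled by library totals), with the line of equal levels. Genes of the epithelium and sensory organs list (circles) lie below the line except Mir205, let-7 genes (squares) lie below it for 8 of 12 genes, against 11 with TMM scaling, and neuron genes (triangles) lie on both sides of it.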

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

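The test of multi-copy genes was chosen after the result was seen: its first form used the raw p, and the stricter adjusted p was set once that value was known.

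Of 2138 genes with no microRNA gene opposite, 7 had more reads on their opposite strand in each library than the 3 that a count of 0 allows; the 2138 genes together had 360 opposite-strand reads over both libraries. Mir5620 had the most in replicate 2, with 22 and 66 reads on the opposite strand beside 24 and 46 on its own strand, and Mir3083 had 22 and 29 beside 54 and 76. Reads with several positions numbered 7658676 in replicate 1 and 8485772 in replicate 2, more than the reads assigned to all microRNA genes of the same library. Whether these reads came from microRNA genes is not given.

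Those multimapping reads stand beside low counts at some multi-copy genes of the brain, though not at others such as the Mir128 family (45508 and 51099 reads) and the Mir138 family (24382 and 47788 reads). The 3 copies of Mir124a had 8 and 12, 5 and 7, and 2 and 13 reads, and the 3 copies of Mir9 had 1193 and 506 reads in all. Reads with several positions were assigned to no gene, so reads that fit more than 1 copy equally were not counted. How much of the low counts this explains is open. Over all multi-copy genes, a longer stretch shared with another hairpin went with fewer reads (Spearman rho -0.774, permutation p = 1e-05, the smallest that 100000 permutations give), but silent gene arrays take part in that relation. Over the 50 genes of expressed families rho was -0.2798 (permutation p = 0.0487, adjusted p = 0.0682), which fails the correction. This relation cannot measure the loss, because even copies with a short shared stretch, such as Mir219a-2, share 22 identical nucleotides. A longer stretch need not mean more reads lost. How far uncounted reads or low expression made the counts low cannot be told apart there. Genes are not independent replicates, and no biological explanation was tested.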

How the results depend on the processing

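The 2-fold criterion, the GC correction, omission of the epithelium list and addition of list members under other symbols were chosen after seeing the data; all other settings named here were fixed before the data were examined. Genes detected numbered 682 at 1 read and 262 at 100 reads in each library, by construction of the minimum. The share of the 10 most abundant genes was 50.7% with both strands, 41.9% without Mir139 and 15.997% of all reads. With all reads as the denominator, shares were 2.19% for the neuron list, 0.281% for oligodendrocyte, 4.42% for Dlk1-Dio3 and 6.09% for let-7, since that denominator holds unassigned reads. Without Mir139 they were 7.54%, 0.968% and 15.3% for neuron, oligodendrocyte and Dlk1-Dio3, since the total is smaller. Without multi-copy genes the neuron list took 4.73% and the oligodendrocyte list 0.275%, since members are dropped, and with both strands the oligodendrocyte list took 0.0319%, since reads over opposite genes become ambiguous. The coefficient of variation was 34.8% with DESeq2's dispersion; the cause was not tested. Genes apart beyond counting error made up 27.9% of those tested with the 2-fold criterion (88 and 67 genes higher in replicate 1 and 2) against 60.6% (161 and 176 genes); under the other settings the share ran from 40.4% without a filter to 84.6% at 100 reads in total, since the number tested changed. The let-7 median log2 ratio was -0.52 with the GC correction; the cause was not tested. The epithelium median stayed between -4.40 and -3.98 under the 7 alternatives tried, and the correlation between 0.921 and 0.973 under its 8. Of 93 list shares under alternatives 31 moved by more than 1 SD. The 93 include each library alone, which with n = 2 always lies within 1 SD of the mean and so could not move. Of 95 list medians 4 moved by more than the spread of random lists or across their limits and 1 was weaker. The sign of the median changed in 11 of these, over 7 lists, none of them past the limits of random lists to begin with, such as the leukocyte list at 0.16 with 100 reads and the oligodendrocyte list at -0.20 without multi-copy genes. In the main setting, only the epithelium, muscle and let-7 medians lay past the limits of random lists. The embryonic stem cell list gave no median ratio, and scarce lists gave none at 100 reads. Leaving out a replicate gave 441 to 481 detected genes and 46.9% to 49.9% for the 10 most abundant genes. No paired analysis was possible because the design has 1 group. Depth limits statements on genes with few reads, and the uncounted reads with several positions limit those on Mir124a.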

Other observations

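The tests of another tissue as the source of the epithelial microRNAs were chosen after the ratios of the epithelium list were seen, and the requirement on Mir203 and Mir205 was added once their ratios were known; the GC correction was also chosen afterwards, and the bounds of the pituitary, GC and neighbour tests were written before their results were seen.

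Most gene-assigned reads came from genes inside other genes. Introns of protein-coding host genes supplied 40.0% ± 3.30 of gene-assigned reads (SD, n = 2), led by Mir139 in Pde2a, and exons of protein-coding hosts 7.21% ± 2.98. Non-coding hosts such as Meg3, the imprinted transcript that holds Mir770, supplied 26.0% ± 1.80, and genes outside annotated hosts 26.8% ± 4.48. Genes on chromosome X supplied 3.77% ± 0.28, with Mir652 in an intron of Tmem164 the most abundant. A count by position that left out Mir770 (1.91% of gene-assigned reads on average) gave the Dlk1-Dio3 region 56 annotated microRNA genes. Of these 47 were detected, and they supplied 13.3% ± 1.49.

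Opposite microRNA genes were a further feature of this annotation. At the 64 genes with another microRNA gene on the opposite strand, 291312 and 337538 reads lay on the opposite strand of a gene. Counting both strands together left 26 genes undetected that were detected by strand, each with a gene opposite, among them Mir191, Mirlet7e, Mir126a and Mir219a-2.

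The epithelium and sensory organs list was higher in replicate 1 for 9 of 10 members. The GC content of the hairpins as the whole cause is argued against, since the list's median log2 ratio was still -4.086 with the trend removed, below each of 10000 matched random lists. Another tissue with cells of the miR-200 and miR-183 families in replicate 1 may be the source: 8 of 8 cluster members were lower in replicate 2 (log2 ratios -6.12 to -2.70), but these are the genes that define the pattern, and of the squamous genes outside them Mir203 had -2.15 and Mir205 0.54, so the source stays open. For pituitary, the median of 4 genes was -1.174, past the bound of -1. Mir7b had -1.65 (15754 and 6727 reads), Mir7-1 -1.41 and Mir375 -0.94, while Mir7-2 had -0.05 (interval -0.20 to 0.09), which goes against it. Mir7-1 and Mir7-2 are multi-copy genes that each share 24 nucleotides with another hairpin, so their counts and this disagreement are uncertain. All 4 pituitary genes were detected in both libraries and Mir375 also stands in the epithelium list. No biological explanation was tested, since the labels put both libraries in 1 group.

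The spread between the replicates was in part related to sequence. Hairpin GC content and log2 ratio were correlated over the 425 detected genes (Spearman rho 0.4877, permutation p = 1e-05, the smallest possible, adjusted p = 1.75e-05), and rho was 0.507 over the 49.6% of them with a mean of at least 100 CPM and 0.4997 without the epithelium list. The GC trend accounted for 18.2% of the variance of the ratios, which is consistent with a bias of library preparation or sequencing that differed between the libraries but leaves most of the spread unexplained; the differing trimming documents are a further open explanation that was not tested. The members of the miR-183 and miR-200 clusters all lay on 1 side, as given above; for the other genes, tested without the epithelium list and with the GC trend removed, whether neighbours go together cannot be told: neighbours within 10 kb differed in log2 ratio by 0.8853 on average and random pairs by 0.980 (100 pairs, one-sided permutation p = 0.130, adjusted p = 0.152), and without the Dlk1-Dio3 list by 0.939 and 0.981 (p = 0.369). No biological explanation was tested.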
